A study of Mus musculus with 8 samples.

How the data were processed

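Gene expression was measured on Affymetrix arrays in memory CD4 T cells of mice, sorted as T follicular helper (Tfh) or T helper 1 (Th1) cells at day 60 after LCMV Armstrong infection from animals labelled Rictor-null or wild-type (WT). There were 8 arrays in 4 groups, 2 biological replicates per group, and each array held RNA pooled from at least 10 mice. Biotin-labelled cRNA had been made from 100 ng of total RNA per array. The labels name spleen as the source. The sort gates, the sex and age of the mice, the scan dates and the part of Rictor that had been deleted are not given in the sources used here.

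The deposited table holds probe set signals as intensity on a linear scale, for 45037 probe sets. The submitters' notes name MAS5 and RMA without a version, a role or an order. The authors' scaling between arrays is not given in words. The 8 columns have close medians and upper quantiles, and exact values recur across columns, as after quantile normalization of probes over these arrays. Detection calls and control probe sets were not in the table, so the planned comparison of 3' and 5' control signals could not be run, and the background correction could not be varied. Depth does not apply to arrays, and the number of arrays limits the precision.

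Signals were taken to log2 after adding a pseudocount of 32. Of the probe sets, 34945 were annotated with 1 gene symbol, 932 with several and 9160 with none. A probe set was kept if it lay above its array's median on at least 2 of the 8 arrays, which left 23725 probe sets, 19671 of them with 1 symbol. Each gene was represented by its brightest probe set, which gave 11217 genes. Positions come from the RefSeq annotation of GRCm38.

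A linear model with 1 mean per group was fitted to all 8 arrays with limma 3.58.1 in R 4.3.3, followed by contrasts and empirical Bayes moderation with default settings (residual degrees of freedom 4, prior degrees of freedom 6.7). The contrasts were Rictor-null minus WT in Tfh cells, the same in Th1 cells, Tfh minus Th1 in WT cells, the same in Rictor-null cells, the difference between the genotype effects of both cell types (the interaction), and their mean. Adjusted p values are from limma with the Benjamini-Hochberg correction over all genes tested in a comparison. A gene is said to have risen or fallen when its adjusted p was under 0.05. A comparison of 2 arrays with 2 arrays by exact permutation cannot give a two-sided p below 0.333, so no permutation test per gene was run. Errors are standard errors (SE) from the fit, and all values are log2 fold changes unless a fold is named.

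The genes named are, for each comparison, the 8 with the largest rise and the 8 with the largest fall among those called whose groups did not overlap (no such condition for the interaction), up to 4 members of each gene list with the smallest p, the brightest 3 members of each list of markers of another cell type, and a fixed set of genes of T cell memory, ferroptosis and sex. RIKEN, clone and receptor segment names were left out. There were 30 gene lists, of which 29 were tested with camera at its preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the lists within a comparison. The estimated setting also rests on the 4 residual degrees of freedom, so its larger p does not measure correlation alone. The estimate lay below the preset for the Tfh signature (-0.0288), the Th1 signature (-0.0213), inhibitory receptors (-0.035) and regulatory T cell markers (-0.079), among others. A list needed at least 5 measured genes, and the list of sex-linked genes was only described. Members that passed the test were counted with p adjusted over all genes and with p adjusted over the list alone. Group definitions, the 30 gene lists, the comparisons with their tests and the naming rule were chosen before the data were examined. Tests and fits chosen later are named as such where they are given.

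The method was tested on simulated data of the same size, in which genes were changed in Tfh cells only. The simulated noise was independent between genes and had the same spread on every array for a gene. In the real data 57.5% of the variance left after the group means lay on a single axis. The simulated rates therefore do not cover correlated genes or a deviating array. At a change of 0.25 log2, 27 of 66 genes (40.9%) were recovered, at 0.5 log2 66 of 67 (98.5%), and at 1 all of 67 genes. Of 174 genes called, 14 had not been changed. A simulated list of 30 genes raised by 0.2 log2 was called with both settings of camera. The preset correlation also called 1 unchanged list, and the estimated correlation called 0.

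Alternatives covered the scaling between arrays, the filter, the pseudocount, the probe set used per gene, array weights, a variance trend, an ordinary linear model, the replicate number as a covariate, the arrays in the fit, and each array left out in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Tcf7 and Ddx3y, which have no probe set annotated with that gene alone, are not analysed here.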

Results

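The data were 8 arrays of memory CD4 T cells from the spleens of mice infected with LCMV Armstrong, a virus strain that the mice clear as an acute infection. T follicular helper (Tfh) cells, which help B cells to make antibody, and T helper 1 (Th1) cells, which make interferon gamma, were compared between mice labelled Rictor-null and wild-type (WT) mice at day 60. Rictor is the subunit that defines mTOR complex 2, a kinase complex that acts on AKT. Each of the 4 groups had 2 arrays, and each array was pooled from at least 10 mice. Median signals per array lay between 35.7 and 37.7 and maximum signals between 16055 and 16327. Each array correlated most closely with the other array of its group, with Pearson r across genes of 0.995 to 0.999, where genes are not independent replicates. The first principal component (40.2% of the variance) placed the Rictor-null arrays at -12.9 to -2.18 and the WT arrays at 3.03 to 12.5. The second (28.6%) placed the Tfh arrays at 2.85 to 11.1 and the Th1 arrays at -11.9 to -1.57. On the third (18.3%), Rictor-null Tfh replicate 2 (-12.4) and WT Th1 replicate 1 (-6.49) had the lowest values. The typical SD between replicates was 0.107 log2 in Rictor-null Tfh cells, 0.0534 in WT Tfh, 0.0729 in Rictor-null Th1 and 0.0807 in WT Th1.

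Rictor (gene ID 78757, chromosome 15, 6708349 to 6800401, GRCm38) was measured by 5 probe sets. Its brightest probe set did not pass the test between genotypes, with 0.02 ± 0.074 log2 (SE, n = 2 arrays per group) in Tfh cells, adjusted p = 0.888, and -0.07 ± 0.074 in Th1 cells, adjusted p = 0.585. Signals of this probe set were 563 and 576 in Rictor-null Tfh, 560 and 563 in WT Tfh, 493 and 474 in Rictor-null Th1, and 468 and 556 in WT Th1. The dimmest Rictor probe set was higher in Rictor-null Tfh cells by 0.31 ± 0.077 (adjusted p = 0.0366), and the other 4 did not pass in either cell type. Where the probe sets lie relative to the deleted part of the gene is not given in the sources used here, so these values do not check the genotype labels.

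The comparison of Rictor-null with WT Tfh cells asks what differs in memory Tfh cells of mice labelled as lacking this subunit. Gzma, which encodes granzyme A of cytotoxic granules (chromosome 13), had the largest rise, 2.28 ± 0.069 log2 or 4.85-fold (SE, n = 2 arrays per group). Folds here and below are of the signal plus 32 and are smaller than folds of the signal itself. Ifitm1, an interferon-induced membrane protein, rose by 1.83 ± 0.065, Prg4, the secreted proteoglycan lubricin, by 1.62 ± 0.063, and Sostdc1, a secreted antagonist of BMP and Wnt signals, by 1.55 ± 0.058. The inhibitory receptor Lag3 rose by 1.43 ± 0.086, the zinc finger factor Plagl1 2.82-fold, Plac8 by 1.43 ± 0.062 and the surface protein Cd83 by 1.29 ± 0.060. Dtx1, a ubiquitin ligase of the Notch pathway (chromosome 5), had the largest fall, -1.05 ± 0.079 or 2.07-fold. The transcription factor Sox4 (-0.94 ± 0.057), the inhibitory receptor gene Klrc1 (-0.78 ± 0.067) and the kinase gene Prkd3 (-0.64 ± 0.064) also fell. As the naming rule required, both Rictor-null arrays lay beyond both WT arrays for each of these genes. Falls of Pik3cd (-0.95), Cab39 (-0.75) and Usp25 (-0.61) rested on the brightest probe set. Other probe sets of Pik3cd gave 0.27 (adjusted p = 0.0437), 0.22 and 0.45 (adjusted p = 0.00213), so 2 of them passed in the opposite direction, another of Cab39 gave 0.00 and another of Usp25 gave -0.06. Igfbp4 fell by -0.61. Of its 5 other probe sets 4 were negative, 1 of them passing (-0.43, adjusted p = 0.00648), and 1 gave 0.01. Other probe sets that did not pass gave -0.19 for Dtx1, -0.15 for Klrc1 and -0.21 and 0.00 for Sox4, while another of Sox4 (-0.43) and that of Prkd3 (-0.40) passed. Over the named genes that passed in Tfh cells, 66 of 76 other probe sets had the same direction and 29 of these passed. The Cab39 call ended without Rictor-null Tfh replicate 2 (adjusted p = 0.0927) or WT Tfh replicate 1 (0.166). That of Usp25 ended without Rictor-null Tfh replicate 2 (0.15), WT Tfh replicate 1 (0.211), WT Tfh replicate 2 (0.0651), Rictor-null Th1 replicate 1 (0.0581) or Rictor-null Th1 replicate 2 (0.0579).

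In total 1528 of 11217 genes passed the limma test in Tfh cells, of which 1269 rose and 259 fell, and 3397 had an unadjusted p under 0.05. The share of rises was 83.0%, and after quantile normalization 63.1% (740 rose and 432 fell). The count was 2820 without Rictor-null Tfh replicate 1, 761 without Rictor-null Tfh replicate 2, 463 without WT Tfh replicate 1 and 506 without WT Tfh replicate 2. Without both arrays with the lowest values on the third component (Rictor-null Tfh replicate 2 and WT Th1 replicate 1) 1054 genes passed (875 rose and 179 fell).

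Genes of the Tfh signature rose as a group in Rictor-null Tfh cells: 20 of 26 measured members rose and 0 fell (21 and 1 adjusted over the list alone), camera adjusted p = 3.85e-11, and 0.0396 with an estimated correlation. Examples were Tox2 (1.12), the cytokine gene Il21 (0.80), the inhibitory receptor gene Pdcd1 (0.77), the chemokine receptor gene Cxcr5 (0.49) and the repressor gene Bcl6 (0.36). Among CD8 T and NK cell markers, 9 of 12 rose and 1 fell (the same counts adjusted over the list alone), including the receptor genes Klre1 (1.17) and Klrk1 (0.46) and the granzyme gene Gzmk (0.54), with adjusted p = 0.00024 and adjusted p = 0.101 with an estimated correlation. Of the lineage genes of CD8 T cells, Cd8b1 rose by 0.28 ± 0.058 (adjusted p = 0.0109) and Cd8a was at -0.07 ± 0.073 (adjusted p = 0.513). Regulatory T cell markers rose in 7 of 12 members with 0 falls (7 and 0 adjusted over the list alone), adjusted p = 4.52e-05 and adjusted p = 0.101 with an estimated correlation. Those that moved include Il10 (1.16), Tnfrsf4 (0.96), Ikzf2 (0.82) and Ctla4 (0.69), which activated T cells can also express. Foxp3, the factor that defines regulatory T cells, lay below the signal filter and had 0.33 ± 0.114 (adjusted p = 0.136 without the filter).

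Inhibitory receptors and exhaustion genes rose in 7 of 13 members in Tfh cells and 1 fell (9 and 1 adjusted over the list alone), with adjusted p = 0.000569 and adjusted p = 0.101 with an estimated correlation. The orphan nuclear receptor gene Nr4a3 (0.93) belongs to this list and to the immediate early and cell-handling stress list. In the latter 12 of 28 rose and 0 fell (14 and 0 adjusted over the list alone), among them Ier3 (0.66) and Atf3 (0.59). Its adjusted p was 0.00624, and adjusted p = 0.161 with an estimated correlation. This call ended without Rictor-null Tfh replicate 1 (adjusted p = 0.35). Interferon-stimulated genes rose in 9 of 25 members with 0 falls (11 and 0 adjusted over the list alone), such as Bst2 (0.90), Ifit3 (0.51), Ifit1 (0.50) and Mx1 (0.41), with adjusted p = 0.00188 and adjusted p = 0.356 with an estimated correlation. Sterol and fatty acid synthesis genes rose in 4 of 21 members with 0 falls (11 and 0 adjusted over the list alone). They were the desaturase gene Scd2 (0.60), Cyp51 (0.38), Fdps (0.37) and Elovl6 (0.36), and the list had adjusted p = 0.00715 and adjusted p = 0.356 with an estimated correlation.

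In Th1 cells the same question was asked of the other memory lineage. Gzma had the largest rise, 3.03 ± 0.069 log2 or 8.14-fold (SE, n = 2 arrays per group). Klre1, a receptor of the NK cell lectin family, rose by 2.10 ± 0.079, Plagl1 by 1.93 ± 0.087, and Fgl2, a prothrombinase-like protein that T cells can secrete, by 1.88 ± 0.084. Klrg1, an inhibitory receptor of terminally differentiated T cells, rose by 1.77 ± 0.071, Prg4 by 1.68 ± 0.063, the fractalkine receptor gene Cx3cr1 by 1.67 ± 0.094 and the sphingosine phosphate receptor gene S1pr5 by 1.59 ± 0.066. Igfbp4, which encodes an insulin-like growth factor binding protein, had the largest fall, -1.19 ± 0.073 or 2.27-fold. Falls followed for Prkd3 (-1.02 ± 0.064), Dtx1 (-0.97 ± 0.079), the co-chaperone gene Dnajc7 (-0.90 ± 0.075), Tesc (-0.90 ± 0.068), the phosphodiesterase gene Pde3b (-0.85 ± 0.056), the chromatin organiser gene Satb1 (-0.83 ± 0.064) and Sox4 (-0.79 ± 0.057). By the same naming rule, both arrays of each genotype lay apart for each of these genes. The other probe set of Dtx1 gave -0.23 and 2 of Sox4 gave -0.11 and -0.08 without passing. Over the named genes that passed in Th1 cells, 59 of 62 other probe sets had the same direction and 38 of these passed.

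In Th1 cells 1180 genes passed the limma test, of which 847 rose and 333 fell, and 2787 had an unadjusted p under 0.05. The share of rises was 71.8%, and 55.4% after quantile normalization (669 rose and 538 fell). The count rose to a similar height without either Rictor-null Tfh array, neither of which enters this contrast. With 1 array left, that group, which had the largest SD between replicates, adds nothing to the shared estimate of spread. Leaving out any other array lowered the count. Without both arrays with the lowest values on the third component it was 1201 (871 rose and 330 fell).

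The Th1 signature rose in Rictor-null Th1 cells in 10 of 28 members with 0 falls (14 and 1 adjusted over the list alone), camera adjusted p = 6.32e-07, and 0.0305 with an estimated correlation. The granzyme gene Gzmb (1.28) and the transcription factor gene Bhlhe40 (0.96) were among them, while Tbx21, the factor that defines Th1 cells, had 0.02 ± 0.056 (adjusted p = 0.842) and Ifng -0.04 ± 0.057 (adjusted p = 0.691). The Tfh signature also rose in Th1 cells, in 14 of 26 members with 2 falls (17 and 2 adjusted over the list alone), for example Sostdc1 (1.00), Cd200 (0.72) and Tox2 (0.71), with adjusted p = 1.82e-08 and 0.0305 with an estimated correlation. Bcl6 and Cxcr5 did not pass (both 0.00). Regulatory T cell markers rose in 8 of 12 members with 0 falls (11 and 0 adjusted over the list alone), such as Nrp1 (0.94), Tnfrsf4 (0.91) and Ctla4 (0.86), with adjusted p = 1.18e-09 and 0.0305 with an estimated correlation. Beside them Foxp3 had 0.28 ± 0.114 (adjusted p = 0.239 without the filter) and Ikzf4, which encodes a partner protein of Foxp3, rose by 0.24 ± 0.055 (adjusted p = 0.0183). Inhibitory receptors and exhaustion genes rose in 8 of 13 and fell in 1 (10 and 1 adjusted over the list alone), led by Lag3 (1.44), with adjusted p = 2.91e-07 and 0.0305 with an estimated correlation. Immediate early and cell-handling stress genes rose in 11 of 28 and fell in 2 (13 and 2 adjusted over the list alone), including Atf3 (0.79), Nr4a3 (0.78) and Fosb (0.54), with adjusted p = 1.14e-05 and 0.0446 with an estimated correlation.

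Proliferation genes rose in 12 of 27 members in Rictor-null Th1 cells with 0 falls (15 and 0 adjusted over the list alone). Mki67 (0.63), the ribonucleotide reductase gene Rrm2 (0.46), Birc5 (0.39) and Cenpa (0.33) were among them, and the list had adjusted p = 1.59e-06 and adjusted p = 0.0518 with an estimated correlation. Chemokine receptors and homing genes rose in 10 of 23 and fell in 1 (11 and 3 adjusted over the list alone), such as the gut-homing receptor gene Ccr9 (1.57) and Cxcr4 (0.79), with adjusted p = 0.000494 and adjusted p = 0.0641 with an estimated correlation. Anti-apoptotic genes rose in 4 of 10 with 0 falls (6 and 0 adjusted over the list alone), namely Pim2 (0.87), Bcl2 (0.50), Birc3 (0.27) and Birc2 (0.25), with adjusted p = 0.000709 and adjusted p = 0.0641 with an estimated correlation. CD8 T and NK cell markers rose in 4 of 12 and fell in 1 (5 and 1 adjusted over the list alone). Besides Gzma and Klre1, Klrd1 rose (0.46) and Klrc1 fell (-0.69), with adjusted p = 0.00317 and adjusted p = 0.0823 with an estimated correlation, while Cd8a was at -0.09 ± 0.073 and Cd8b1 at 0.00 ± 0.058. FOXO targets rose in 6 of 20 with 0 falls (6 and 1 adjusted over the list alone), including Klf4 (0.66), Trib2 (0.47) and Bcl2l11 (0.42), with adjusted p = 0.00928 and adjusted p = 0.0987 with an estimated correlation. Sterol and fatty acid synthesis genes rose in 8 of 21 with 0 falls (9 and 0 adjusted over the list alone), such as Scd2 (0.67) and Hmgcs1 (0.46), with adjusted p = 0.0128 and adjusted p = 0.308 with an estimated correlation. Interferon-stimulated genes rose in 6 of 25 and fell in 1 (7 and 1 adjusted over the list alone), with Ifi27l2a at 0.55 and Ifit3 at 0.48, adjusted p = 0.0397 and adjusted p = 0.523 with an estimated correlation. This interferon-stimulated call ended after quantile normalization (adjusted p = 0.0698) and without Rictor-null Th1 replicate 1 (0.113), WT Th1 replicate 1 (0.057) or WT Th1 replicate 2 (0.0585).

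**Figure D1:**
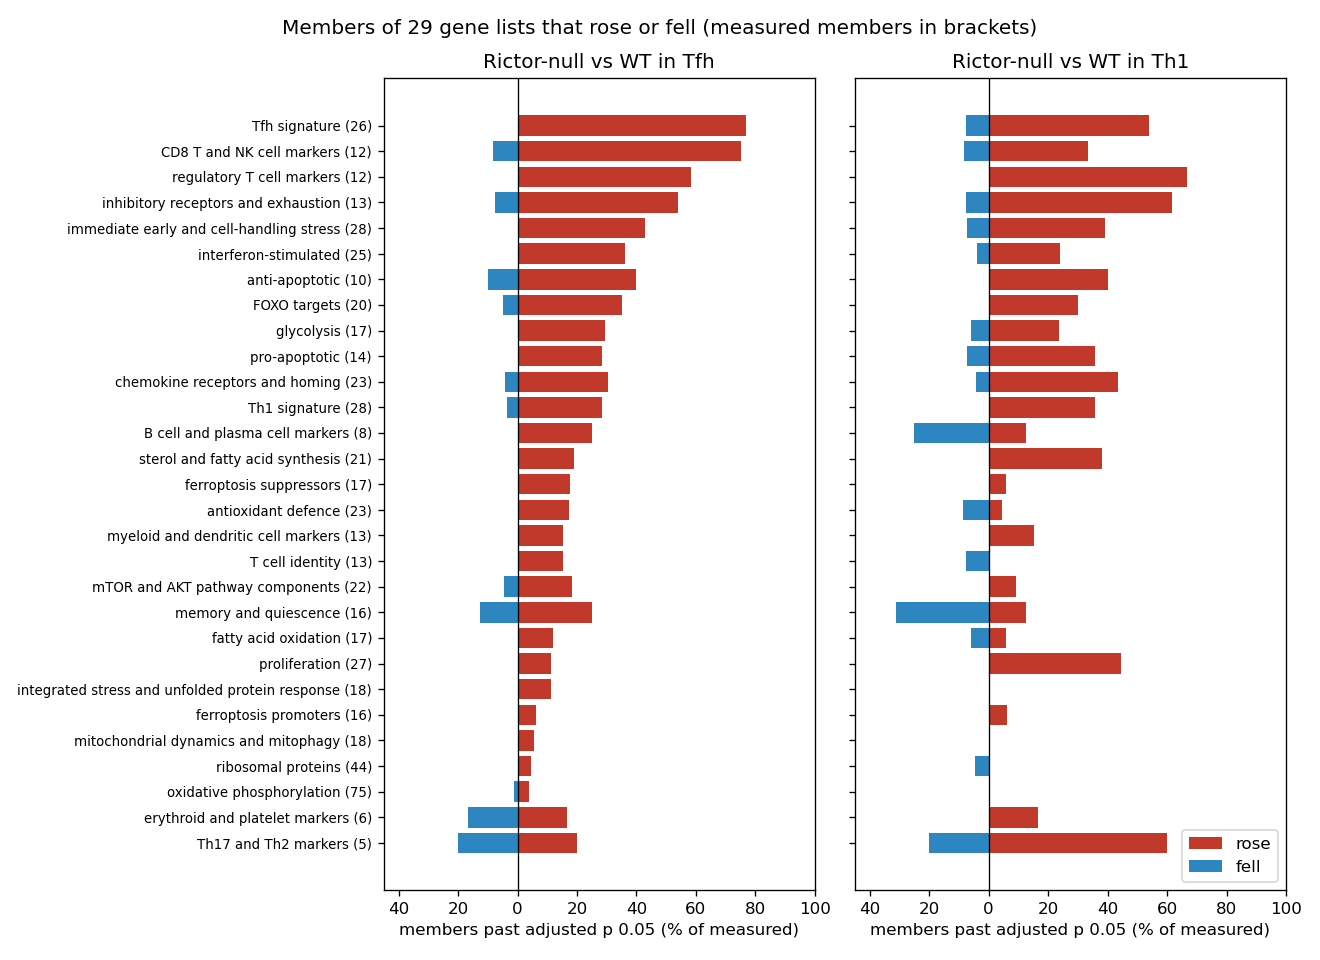
Percent of the measured members of 29 gene lists that rose (red, to the right) or fell (blue, to the left) at adjusted p under 0.05 in Rictor-null against WT cells, Tfh cells in the left panel and Th1 cells in the right, with the number of measured members in brackets. In Tfh cells 20 of the 26 Tfh signature genes rose, and in Th1 cells 14 of them rose.

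Several groups did not pass the camera test in 1 or both cell types. Fry, which asks whether a list moves without comparing it with other genes, is given beside it. Of the mTOR and AKT pathway components, 4 of 22 rose and 1 fell in Tfh cells (adjusted p = 0.474, fry 0.00418), and 2 rose in Th1 cells (adjusted p = 0.681, fry 0.225). Prr5l, which encodes a protein that binds mTOR complex 2, rose in both, by 0.89 ± 0.084 and 1.33 ± 0.084. Memory and quiescence genes rose in 4 of 16 and fell in 2 in Tfh cells, and rose in 2 and fell in 5 in Th1 cells (adjusted p = 0.601 and 0.168, fry 0.0457 and 0.00396). Bcl2 rose in both cell types (0.68 and 0.50) and the repressor gene Bach2 fell in both (-0.37 and -0.58), while Id3 rose in Tfh cells (0.69). Glycolysis genes rose in 5 of 17 in Tfh cells, and rose in 4 and fell in 1 in Th1 cells (adjusted p = 0.19 and 0.32, fry 0.00507 and 0.034), with the glucose transporter gene Slc2a3 (0.54 and 0.60) and Tpi1 (0.50 and 0.25) in both. Of 75 oxidative phosphorylation genes, 3 rose and 1 fell in Tfh cells (adjusted p = 0.535, fry 0.113), and in Th1 cells 0 passed the limma test and 2 had an unadjusted p under 0.05 (camera adjusted p = 0.403, fry adjusted p = 0.758). Pro-apoptotic genes rose in 4 of 14 in Tfh cells, and rose in 5 and fell in 1 in Th1 cells (adjusted p = 0.474 and 0.0959, fry 0.00355 and 0.00261), with Pmaip1 (0.42 and 0.84), Bcl2l11 (0.26 and 0.42) and Bid (0.38 and 0.41) in both. In Tfh cells the Th1 signature had 8 rises and 1 fall among 28 (adjusted p = 0.19, fry 6.49e-05), among them Klrg1 (1.15), Cx3cr1 (1.15), Bhlhe40 (0.95) and Gzmb (0.73). Also in Tfh cells, homing genes had 7 rises and 1 fall among 23 (adjusted p = 0.235, fry 0.0011), with S1pr5 (1.09) and Ccr9 (0.95), FOXO targets 7 rises and 1 fall among 20 (0.165, fry 0.00206), anti-apoptotic genes 4 rises and 1 fall among 10 (0.174, fry 0.000413), and proliferation genes 3 rises among 27 (0.113, fry 0.00583).

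The effects of genotype in both cell types were then set side by side. Among genes that rose, 500 did so in Tfh and in Th1 cells where independent calls would give 95.8, and among those that fell 58 did where 7.69 would be given, while 29 moved in opposite directions. Both comparisons use the same estimate of spread per gene, so calls would overlap more than independent ones even without a shared effect. The log2 fold changes of both comparisons, which share no arrays, had Pearson r = 0.474 and Spearman rho = 0.292 across 11217 genes, where genes are not independent replicates. Across the 2121 genes that passed in either, r was 0.613 and rho 0.498. Over all genes Pearson r was 0.296 without Rictor-null Tfh replicate 1 and 0.624 without Rictor-null Tfh replicate 2. Averaged over both cell types, Gzma rose by 2.65 ± 0.049, Plagl1 by 1.72 ± 0.061, Prg4 by 1.65 ± 0.044, Klre1 by 1.63 ± 0.056 and Ifitm1 by 1.60 ± 0.046 (SE, n = 4 arrays per genotype). Dtx1 (-1.01 ± 0.056), Igfbp4 (-0.90 ± 0.051), Sox4 (-0.87 ± 0.040) and Prkd3 (-0.83 ± 0.045) fell most. By camera 12 gene lists passed in the average, and with an estimated correlation the Tfh signature (adjusted p = 0.0358) and regulatory T cell markers (adjusted p = 0.0441) did. In this average 1916 genes passed the limma test, with 1475 rises and 441 falls (77.0% rises, and 54.0% after quantile normalization with 989 rises and 841 falls). The count was 1154 without WT Tfh replicate 1, 1040 without WT Tfh replicate 2 and 1247 without Rictor-null Th1 replicate 1, and 1825 without both arrays with the lowest values on the third component.

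**Figure D2:**
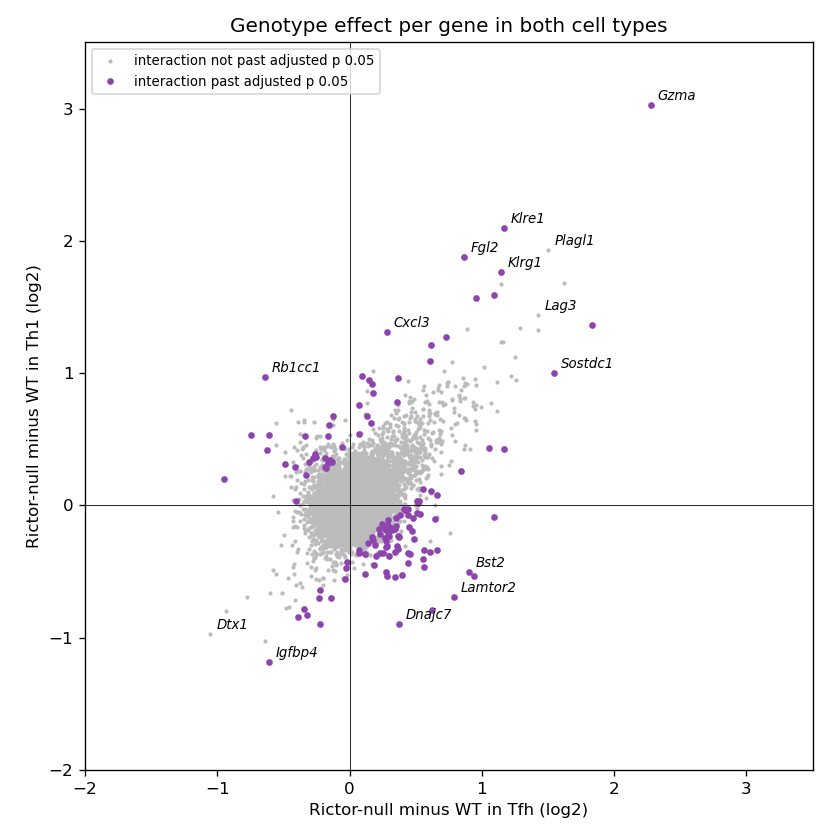
Log2 fold change of Rictor-null over WT cells for each of 11217 genes in Tfh cells (horizontal axis) and in Th1 cells (vertical axis), with purple points for the 136 genes whose effects differed between the cell types at adjusted p under 0.05. Gzma lies at 2.28 and 3.03, and Lamtor2 at 0.79 and -0.69.

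The interaction asks where the effect of genotype differed between Tfh and Th1 cells, and 136 genes passed it, 92 with a higher and 44 with a lower effect in Tfh cells. Lamtor2, a subunit of the Ragulator complex that anchors mTOR complex 1 at lysosomes, rose in Tfh cells (0.79) and fell in Th1 cells (-0.69), a difference of 1.48 ± 0.114 (SE, n = 2 arrays per group, adjusted p = 0.000379). The same opposite pattern held for Swi5 (0.94 and -0.53), Taf7 (0.62 and -0.79), the interferon-induced tethering factor gene Bst2 (0.90 and -0.50), Dnajc7 (0.37 and -0.90), the chloride channel gene Clic1 (0.56 and -0.47) and the antiproliferative gene Btg2 (0.66 and -0.34). Pdia3, a disulfide isomerase of the endoplasmic reticulum, rose in Tfh cells (1.10) and had -0.08 in Th1 cells. Each of these values is from the brightest probe set. The other probe set passed in neither cell type for Lamtor2 (-0.15 and -0.11), Taf7 (-0.17 and -0.04), Btg2 (0.01 and 0.00) and Pdia3 (-0.05 and 0.04). Swi5, Bst2, Dnajc7 and Clic1 had no other. A larger rise in Th1 cells was measured for the neutrophil chemokine gene Cxcl3 (0.28 in Tfh and 1.31 in Th1 cells), Fgl2 (0.86 and 1.88), Klre1 (1.17 and 2.10) and Gzma (difference -0.75 ± 0.097). Il10 rose more in Tfh cells (1.16 and 0.42). Tmem176a rose in Th1 cells (0.98) and had 0.10 in Tfh cells. For Bcl6 (difference 0.35, adjusted p = 0.0628) and Cxcr5 (0.49, adjusted p = 0.0883) the interaction did not pass. The differences of Rb1cc1 (-1.61 ± 0.333, adjusted p = 0.0486), Cab39 (-1.28 ± 0.251), Pik3cd (-1.14 ± 0.236) and Usp25 (-1.14 ± 0.225) had the largest errors among the genes with the largest differences and lay near the threshold. Other probe sets gave 0.16 in Tfh and 0.04 in Th1 cells for Rb1cc1, 0.00 and 0.05 for Cab39, and -0.06 and -0.13 for Usp25. Those of Pik3cd were positive in both. Leaving out any single array of WT Tfh, Rictor-null Th1 or WT Th1 cells ended the calls of Rb1cc1 (adjusted p of 0.0747 to 0.237), Pik3cd (0.102 to 0.217) and Usp25 (0.0551 to 0.211). That of Cab39 ended without any array (0.0514 to 0.207) other than Rictor-null Tfh replicate 1 and WT Th1 replicate 1. The Taf7 call ended without WT Tfh replicate 1 (0.0902) or Rictor-null Th1 replicate 1 (0.112), and that of Pdia3 without WT Tfh replicate 1 (0.0606), WT Tfh replicate 2 (0.0735) or Rictor-null Th1 replicate 2 (0.0535).

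Among gene lists, the Th1 signature had a lower effect in Tfh than in Th1 cells, with 0 members higher and 3 lower (1 and 5 adjusted over the list alone), namely Klrg1 (-0.62), Gzmb (-0.55) and the integrin gene Itgb1 (-0.50). Its adjusted p was 0.000219, and adjusted p = 0.21 with an estimated correlation. Proliferation genes (0 members passing limma, also adjusted over the list alone, 6 of 27 with an unadjusted p under 0.05, adjusted p = 0.00315 and fry adjusted p = 0.104) and homing genes (0 higher and 3 lower, 2 and 8 adjusted over the list alone, adjusted p = 0.00315) went the same way. So did Th17 and Th2 markers (0 higher and 1 lower of 5, Il17a at -0.55, 0 and 2 adjusted over the list alone, adjusted p = 0.0139). All of these last 3 had adjusted p = 0.249 with an estimated correlation and 0.0919 without Rictor-null Tfh replicate 1, and Th17 and Th2 markers had 0.113 without WT Th1 replicate 2. Without Rictor-null Th1 replicate 1 or 2 the Th17 and Th2 markers had fewer than 5 measured genes and were not tested.

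The count of 136 differing genes moved by more than 1.5 times with each of the 8 arrays left out. It was 1602 without Rictor-null Tfh replicate 1, 89 without Rictor-null Tfh replicate 2, 27 and 30 without WT Tfh replicates 1 and 2, 29 and 47 without Rictor-null Th1 replicates 1 and 2, and 77 and 60 without WT Th1 replicates 1 and 2. Without both arrays with the lowest values on the third component 156 genes passed, of which 102 were among the 136, and an ordinary linear model without moderation called 1 gene.

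Tfh and Th1 cells of WT mice were compared to describe the lineages themselves and to check their labels by known Tfh and Th1 genes. Eomes, a T-box transcription factor gene of cytotoxic and memory T cells (chromosome 9), was higher in Tfh cells by 3.18 ± 0.075 log2 or 9.07-fold (SE, n = 2 arrays per group). Also higher in Tfh cells were the transcription factor gene Myb (1.56 ± 0.057), the granzyme genes Gzmk (1.56 ± 0.092) and Gzma (1.38 ± 0.069), the Tfh chemokine receptor gene Cxcr5 (1.36 ± 0.086) and Sox4 (0.93 ± 0.057). Ctla2a (1.12 ± 0.274) and Pik3cd (0.93 ± 0.167) were higher too. The Ctla2a call ended without WT Tfh replicate 1 (adjusted p = 0.164), WT Tfh replicate 2 (0.0985) or WT Th1 replicate 1 (0.161). That of Pik3cd ended without WT Tfh replicate 1 (0.0717), and its 3 other probe sets gave -0.10, -0.09 and -0.17. Igfbp4 was lower in Tfh cells by -2.21 ± 0.073, or 4.64-fold, as were Pdlim4 (-1.85 ± 0.101), the sialyltransferase gene St8sia6 (-1.07 ± 0.074), Treml2 (-0.96 ± 0.065), the integrin gene Itgb3 (-0.91 ± 0.072), Fosl2 of the AP-1 family (-0.90 ± 0.075) and the T cell receptor adaptor gene Trat1 (-0.87 ± 0.083). Ramp1 was lower by -0.90 ± 0.064 on its brightest probe set, and another gave 0.11. Others gave -0.15 for Itgb3, -0.03 for Fosl2 and 0.02 for 1 of 3 of Sox4 without passing. Over the named genes that passed here, 47 of 58 other probe sets had the same direction and 28 of these passed. Tbx21 had -0.07 ± 0.056 (adjusted p = 0.425) and Ifng 0.09 ± 0.057 (adjusted p = 0.274), so these Th1 genes gave the Th1 label no support.

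By list, CD8 T and NK cell markers were higher in WT Tfh cells in 8 of 12 and lower in 0 (9 and 2 adjusted over the list alone), with camera adjusted p = 4.46e-12 and 0.0425 with an estimated correlation, while Cd8a had 0.03 (adjusted p = 0.776) and Cd8b1 -0.19 (adjusted p = 0.0503). The Tfh signature was higher in 13 of 26 and lower in 7 (13 and 7 adjusted over the list alone), with Cxcr5, Pou2af1 (0.88), Sostdc1 (0.77), the signalling adaptor gene Sh2d1a (0.69) and Bcl6 (0.48) higher. Its 7 lower members are counted but not named here. The Th1 signature was higher in 8 of 28 and lower in 2 (8 and 2 adjusted over the list alone), and its higher members were led by Eomes, Gzmb (0.66), Klrg1 (0.61) and the granule gene Nkg7 (0.45). In WT cells most members of the Th1 signature that passed thus lay opposite to the labels, with a list median of 0.03. This did not hold in Rictor-null cells, given below. Proliferation genes were higher in 5 of 27 and lower in 1 (9 and 1 adjusted over the list alone), with Ube2c (0.38) and Rrm2 (0.37). These lists had adjusted p of 1.76e-05, 0.000588 and 3.03e-06, and each had adjusted p = 0.082 with an estimated correlation. Myeloid and dendritic cell markers were higher in 2 of 13 and lower in 0 (4 and 0 adjusted over the list alone), Cd68 at 0.38 and Fcer1g at 0.22, with adjusted p = 0.00345, adjusted p = 0.207 with an estimated correlation and 0.144 without WT Tfh replicate 2. Immediate early and cell-handling stress genes were lower in 12 of 28 and higher in 1 (13 and 2 adjusted over the list alone), such as Atf3 (-0.78) and Zfp36 (-0.39), with adjusted p = 0.0365 and adjusted p = 0.234 with an estimated correlation. In WT cells the call of the immediate early and cell-handling stress list ended without Rictor-null Tfh replicate 1 (0.0884), Rictor-null Tfh replicate 2 (0.0873) or WT Tfh replicate 2 (0.0656).

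Between the WT lineages 1653 genes passed, 347 higher and 1306 lower in Tfh cells (21.0% higher), and after quantile normalization 1008 (407 higher and 601 lower, 40.4% higher). The count was 2669 and 2656 without Rictor-null Tfh replicates 1 and 2, 196 and 270 without WT Tfh replicates 1 and 2, 382 and 646 without WT Th1 replicates 1 and 2, and 1479 without both arrays with the lowest values on the third component.

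The same contrast in Rictor-null cells asks how the lineages differ in mice with that label. Eomes was higher in Tfh cells by 3.31 ± 0.075 or 9.92-fold (SE, n = 2 arrays per group), Gzmk by 1.98 ± 0.092, Cxcr5 by 1.85 ± 0.086, Myb by 1.57 ± 0.057, Tox2 by 1.32 ± 0.078, Sostdc1 by 1.31 ± 0.058, Ifitm1 by 1.13 ± 0.065 and the chemokine gene Ccl3 by 1.03 ± 0.064. Igfbp4 (-1.64 ± 0.073, or 3.11-fold), Pdlim4 (-1.51 ± 0.101), the aryl hydrocarbon receptor gene Ahr (-1.42 ± 0.070), St8sia6 (-1.40 ± 0.074), the cytokine signalling inhibitor gene Socs2 (-1.37 ± 0.082), St8sia1 (-1.27 ± 0.086), Fgl2 (-1.17 ± 0.084) and Tmem176b (-1.16 ± 0.071) were lower. Over the named genes that passed here, 52 of 56 other probe sets had the same direction, 30 of these passed, and 1, of Btg2, passed in the opposite direction. Among those that did not pass were 1 of Socs2 (-0.13) and 1 of Igfbp4 (0.03). Prdm1, which encodes the factor Blimp-1, was lower by -0.28 ± 0.060 (adjusted p = 0.0147), Il7r by -0.29 ± 0.061, Ccr7 by -0.57 ± 0.055 and Cxcr6 by -0.58 ± 0.117. The call of Cxcr6 ended without Rictor-null Tfh replicate 2 (adjusted p = 0.0532) or Rictor-null Th1 replicate 2 (0.105), and that of Prdm1 without Rictor-null Tfh replicate 2 (0.0514) or Rictor-null Th1 replicate 1 (0.122). The Il7r call ended after quantile normalization (0.0645) and without Rictor-null Th1 replicate 1 (0.0762) or 2 (0.0841).

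By list, CD8 T and NK cell markers were higher in Rictor-null Tfh than Th1 cells in 7 of 12 and lower in 1 (7 and 1 adjusted over the list alone), with camera adjusted p = 1.58e-09 and 0.043 with an estimated correlation. Prf1, the perforin gene (0.94), was among them. The Tfh signature was higher in 13 of 26 and lower in 6 (15 and 6 adjusted over the list alone), with adjusted p = 1.16e-07 and 0.043 with an estimated correlation. The Th1 signature was higher in 2 of 28 and lower in 8 (5 and 9 adjusted over the list alone), with a median of -0.05. It did not pass camera (adjusted p = 0.735), and fry called it higher (adjusted p = 0.0193). Th17 and Th2 markers were lower in 3 of 5 with 0 higher (3 and 0 adjusted over the list alone), namely Gata3 (-0.78), Il17a (-0.47) and Ccr6 (-0.46), adjusted p = 0.00419 and adjusted p = 0.17 with an estimated correlation. Without Rictor-null Th1 replicate 1 or 2 that list had fewer than 5 measured genes and was not tested. FOXO targets were lower in 9 of 20 and higher in 1 (11 and 3 adjusted over the list alone), with Tsc22d3 at -0.67, adjusted p = 0.0064 and adjusted p = 0.17 with an estimated correlation. Homing genes were lower in 9 of 23 and higher in 2 (12 and 4 adjusted over the list alone), with Ccr9 at -0.86 and Itgae at -0.84, adjusted p = 0.0111. Immediate early and cell-handling stress genes were lower in 10 of 28 and higher in 4 (14 and 5 adjusted over the list alone), with Atf3 at -0.98, adjusted p = 0.00931. Both lists had adjusted p = 0.177 with an estimated correlation, and the immediate early call ended without Rictor-null Tfh replicate 2 (0.0996) or Rictor-null Th1 replicate 2 (0.0676). Oxidative phosphorylation passed in the direction of higher signal (adjusted p = 0.00931) with 0 of 75 members passing limma (0 also adjusted over the list alone, 7 with an unadjusted p under 0.05). It had adjusted p = 0.773 with an estimated correlation, 0.367 with fry, 0.111 with the mean of all probe sets and 0.32 without Rictor-null Th1 replicate 2. Myeloid and dendritic cell markers were higher in 3 of 13 with 0 lower (5 and 0 adjusted over the list alone), adjusted p = 0.041 and adjusted p = 0.345 with an estimated correlation. The call of the myeloid and dendritic cell markers ended after quantile normalization (0.169), with the mean of all probe sets (0.185), without the filter (0.0775) and with the replicate block (0.0519). It also ended without Rictor-null Tfh replicate 1 (0.149), Rictor-null Th1 replicate 2 (0.203), WT Th1 replicate 1 (0.0534) or WT Th1 replicate 2 (0.0544).

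Between the Rictor-null lineages 1090 genes passed, 367 higher and 723 lower in Tfh cells (33.7% higher, and 44.4% after quantile normalization with 440 higher and 550 lower). The count was 1641 without Rictor-null Tfh replicate 1, 387 and 534 without Rictor-null Th1 replicates 1 and 2, and 1147 without both arrays with the lowest values on the third component. In both genotypes 104 genes were higher in Tfh cells and 302 lower, where independent calls would give 11.4 and 84.2, and 33 passed in opposite directions. These calls also share the estimate of spread per gene, so they are not independent.

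**Figure D3:**
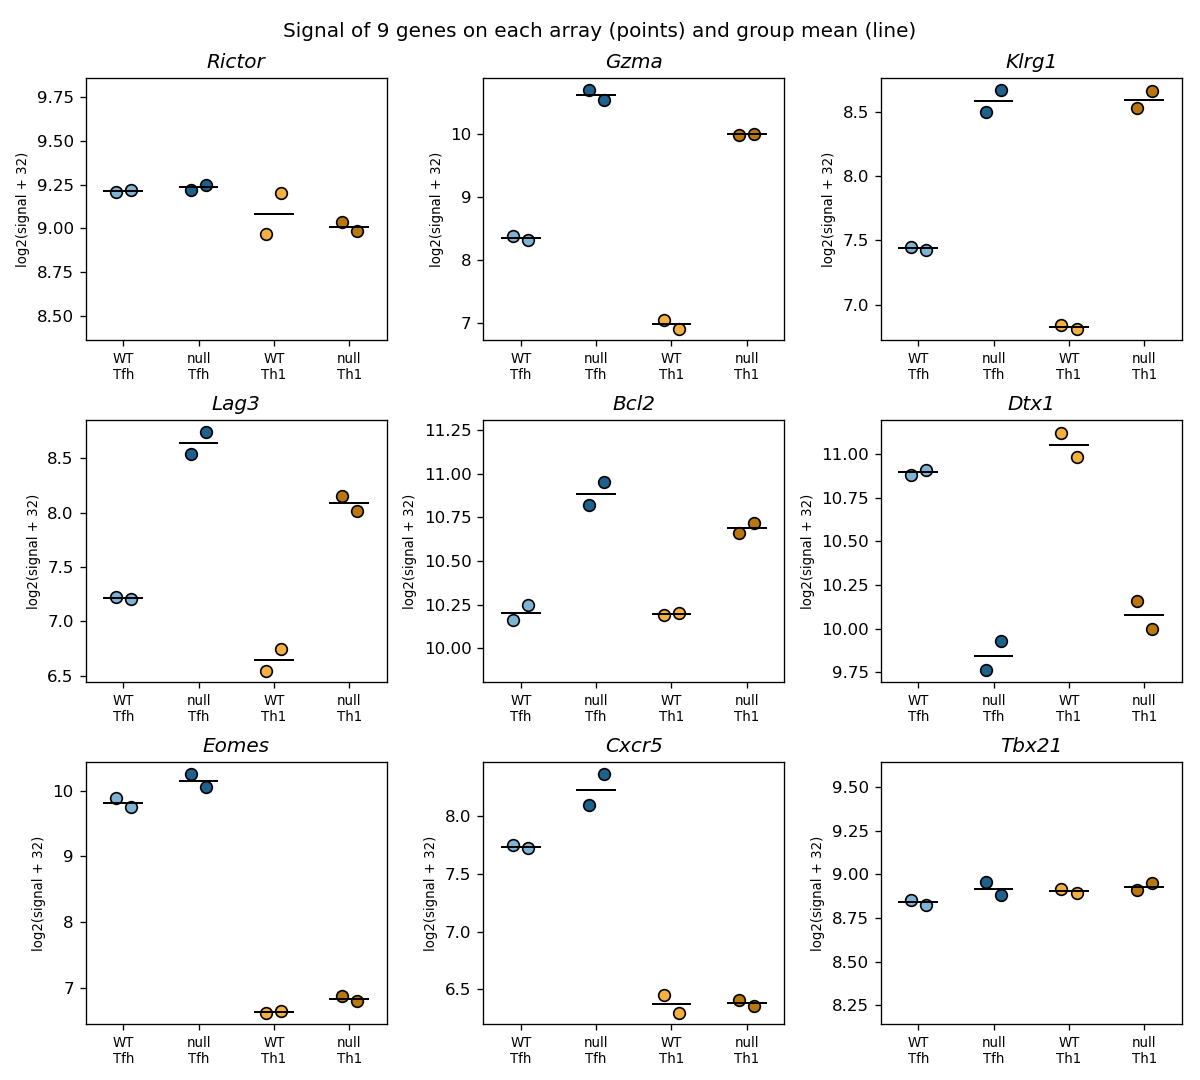
Signal of 9 genes on each of the 8 arrays (points, log2 of signal plus 32) with the group mean (line) for WT and Rictor-null Tfh and Th1 cells. Gzma lay at 8.32 to 8.38 in WT Tfh and 10.55 to 10.70 in Rictor-null Tfh cells, and at 6.91 to 7.04 in WT Th1 and 9.98 to 10.01 in Rictor-null Th1 cells, while Tbx21 lay between 8.83 and 8.96 on all 8 arrays.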

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

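The tests of the share of rises after quantile normalization, of the interaction without a pair of arrays, of the genes passing without either Rictor-null Tfh array, and of CD8 T cell and regulatory T cell markers were chosen only after the result was seen.

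Averaged over both cell types, 1916 genes passed between the genotypes, and 77.0% of them rose. Of the 35 splits of the 8 arrays into 4 and 4, 2 called as many genes, the genotype split included, so this count alone does not exclude chance. The other was the split by cell type with 2247, the study's second factor. The next, with 136, was the split that forms the interaction, also a contrast of the design. Every further split called at most 2 genes. Such splits leave the genotype effect in their residuals, which lowers their counts, so these counts do not measure chance. Of the 110 tested neighbours of Rictor 17.3% were called, against 17.1% of other genes (Fisher exact p = 0.899). This argues against a local effect of DNA carried along with the mutant allele on those neighbours. They held 0.992% of the calls, a share that decides nothing, since so few genes could not hold most of the calls. An effect of such DNA on genes elsewhere was not tested and stays open. After quantile normalization 54.0% of the calls were rises, with 1830 genes still passing. That normalization would also reduce a true excess of rises, so it cannot tell scaling between arrays from biology. Centring arrays on their median raised the share from 83.0% to 86.8% in Tfh and from 71.8% to 79.6% in Th1 cells. Scaling stays open for the excess of rises. An effect of genotype on these genes stays open as the biological explanation.

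The effect of genotype differed between Tfh and Th1 cells by the interaction test in 136 genes. Rictor-null Tfh replicate 2 alone is argued against for 87 of them, which passed in the same direction without it and also without replicate 1, and the scaling between arrays is argued against by a median size of these differences of 0.962 of that before quantile normalization (quartiles 0.938 to 1.02), with 120 of the genes still passing. That array stays open for the other 49 genes, and so does the within-group axis that sets it and WT Th1 replicate 1 apart: the median size was 0.942 without the array and 0.933 without both, but the genes were chosen with these arrays, which favours ratios near 1, so the bound set for these ratios decides nothing. Rictor-null Tfh replicate 2 minus 1 correlated with the interaction at r = 0.591 across all genes, and the count ran from 27 without WT Tfh replicate 1 and 89 without Rictor-null Tfh replicate 2 to 1602 without Rictor-null Tfh replicate 1. The result on scaling covers only what a further quantile normalization of the table could remove. That step moved the median interaction over all genes only from 0.04 to 0.0197. Scaling done before the table was made was not varied and stays open. A difference in biology between the lineages also stays open, as untested.

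In the genotype average 9 of 12 CD8 T and NK cell markers rose and 1 fell (camera adjusted p = 0.000152, and 0.0618 with an estimated correlation), with the largest rise for Gzma at signals of 87.8 to 1630 over the arrays. NK cells among the sorted cells cannot be told apart from a change within CD4 T cells: 5 NK markers had a median of 0.024 log2 averaged over both cell types, but 4 of them lay below the signal filter, where the pseudocount of 32 holds any change small, so the bound of 0.2 set for this median decides nothing. CD8 T cells also stay open, because the 2 markers had a median of 0.0275 and went opposite ways (Cd8a -0.08, Cd8b1 0.14). Regulatory T cells also stay open, with a median of 0.155 over 4 markers, where Il2ra (0.15) and Ikzf4 (0.16) rose and Foxp3, below the filter, had 0.30 (adjusted p = 0.0594). A sort on CD4 would remove CD8 T and NK cells but not regulatory T cells, the gates are not given in the sources used here, and an effect of genotype within the cells stays open and untested.

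Single genes passed the interaction test with these differences in log2 fold change, Tfh minus Th1: Lamtor2 1.48, Swi5 1.48, Taf7 1.41, Bst2 1.40, Dnajc7 1.27, Pdia3 1.18, Clic1 1.03 and Btg2 0.99 were higher in Tfh cells. Lower in Tfh cells were Rb1cc1 -1.61, Cab39 -1.28, Pik3cd -1.14, Usp25 -1.14, Cxcl3 -1.03, Fgl2 -1.02, Klre1 -0.93 and Tmem176a -0.88. Other probe sets of Lamtor2, Taf7, Btg2, Pdia3, Rb1cc1, Cab39, Pik3cd and Usp25 did not move apart in this way. Among gene lists the interaction passed for the Th1 signature (adjusted p = 0.000219), proliferation (0.00315), chemokine receptors and homing (0.00315) and Th17 and Th2 markers (0.0139), and with an estimated correlation for 0 lists.

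Probe sets with no gene listed, which no comparison above uses, also differed between genotypes: 374 of 3480 in Tfh cells (10.7%, against 9.94% of probe sets with a gene) and 349 in Th1 cells (10.0% against 8.53%).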

How the results depend on the processing

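The fits without a pseudocount, with the crossed replicate block, with the residual axis as a covariate and without both Rictor-null Tfh replicate 2 and WT Th1 replicate 1 were chosen after seeing the data. Of the values of single named genes under all alternatives, 4184 counted as the same. Called values among them kept the call and direction, and uncalled ones moved by less than the SE, without a check of their sign. A further 156 lost the call, 50 gained it and 82 uncalled values moved by the SE or more. Another 4 reversed, counted only where either fit made a call. Centring each array on its median, the variance trend, a pseudocount of 100 and the mean of all probe sets kept each count of genes within 1.5 times its value. Scaling moved the median of all genes by less than 0.1 log2 in each comparison. The cause was not tested for any change below unless given.

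Counts of genes that moved were, for Rictor-null against WT Tfh cells (1528), 987 with the filter at the 75th percentile, 483 with an ordinary linear model and 933 with only the groups compared. For Th1 cells (1180) the linear model gave 406. For Tfh against Th1 in WT cells (1653) quantile normalization gave 1008, the 75th percentile 1076, array weights 3175, the linear model 238 and only the groups compared 2589. For Rictor-null lineages (1090) array weights gave 660, the linear model 280 and only the groups compared 580. For the interaction (136) no filter gave 65, the 75th percentile 86, the linear model 1, a pseudocount of 1 gave 73 and no pseudocount 72. For the genotype average (1916) the 75th percentile gave 1240, with fewer genes tested, and the linear model 988. The linear model borrows no spread from other genes.

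With the replicate number as a block the counts were 1111, 952, 1003, 796, 91 and 1586, in the same order. Replicate differences correlated positively between the genotypes of a lineage (0.276 in Tfh and 0.172 in Th1 cells). Between Tfh and Th1 groups they correlated at -0.514 to 0.00318, so the numbers show no pairing over all groups. A pairing of the genotypes within a lineage stays open. A crossed block, with replicate 1 of Tfh joined to replicate 2 of Th1 groups, gave 2364, 1939, 2725, 1764 and 736 for the first 5, and the residual axis gave 3291, 2526, 3742, 2441, 1609 and 3338. Both were chosen from the same residuals that they remove, which inflates these counts.

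With 1 array left out, where the lone array of a group is assumed to vary like the others, counts ran from 463 to 2820 for Tfh, 560 to 1771 for Th1, 196 to 2669 for WT lineages, 387 to 1641 for Rictor-null lineages, 27 to 1602 for the interaction and 1040 to 2425 for the average. The highest counts were without Rictor-null Tfh replicate 1. For Th1 cells and for WT lineages, whose contrasts do not use Rictor-null Tfh arrays, the counts without replicate 2 were close to these. The lowest were without WT Tfh replicate 1 (Tfh, WT lineages, interaction), Rictor-null Th1 replicate 1 (Th1, Rictor-null lineages) and WT Tfh replicate 2 (average). The correlation of both genotype effects (0.474) ran from 0.296 to 0.624.

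Rictor ran from 0.00365 to 0.0344 in Tfh and from -0.191 to 0.0428 in Th1 cells with 1 array left out. In Th1 cells it was -0.191 without both arrays named above, 0.0067 as the mean of probe sets, and 0.118, 0.0182 and 0.085 on 3 of its other probe sets. In Tfh cells its dimmest probe set passed at 0.305. Igfbp4 in Tfh cells was 0.00789 with only the groups compared, where another probe set becomes the brightest. As reported, Xist did not pass between Rictor-null lineages (-0.0442) or in the interaction (-0.0116). It passed limma in the opposite direction on other probe sets. Between Rictor-null lineages it was 0.412 as the mean of probe sets (adjusted p = 0.0044). Without probe sets that can cross-hybridise it was 0.905 (adjusted p = 0.000332), and the interaction was 0.895 (adjusted p = 0.0171).

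Gene lists passing camera were 7, 12, 6, 8, 4 and 12 in the same order, and 1, 5, 1, 2, 0 and 2 with an estimated correlation. The latter setting also rests on the 4 residual degrees of freedom, so the drop does not measure correlation between genes alone. Fry gave 19 for Tfh, 13 for WT lineages and 20 for the average, and asks another question. No filter gave 15 for Tfh, 10 for WT lineages and 9 for the interaction, and quantile normalization 8 for the interaction. With 1 array left out they ran from 6 to 7, 11 to 12, 4 to 7, 4 to 8, 1 to 7 and 12 to 12. Without either Rictor-null Th1 array the Th17 and Th2 markers were not tested, with fewer than 5 genes past the filter. Median signals of 35.7 to 37.7 lie close to the pseudocount of 32, which shrinks folds of dim genes. Another background correction and the comparison of 3' with 5' control probe sets were not run, since both need values not used here.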

Other observations

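No test of an explanation is reported in this part, and the values are given as measured.

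Genes that guard against ferroptosis, a form of death by lipid peroxidation, did not pass camera as a group between the genotypes, while fry called the suppressors (adjusted p = 0.0471) and the promoters (0.0304) higher in the average of both cell types. Of 17 ferroptosis suppressors 3 rose in Tfh cells (adjusted p = 0.867 by camera, fry 0.0968), namely the cystine transporter subunit gene Slc3a2 (0.36 ± 0.065), Gch1 (0.27 ± 0.072) and Mboat1 (0.24 ± 0.066), and 1 rose in Th1 cells (Slc3a2, 0.23 ± 0.065, adjusted p of the list 0.32, fry 0.133). Gpx4, the lipid peroxide reductase, had 0.13 ± 0.067 in Tfh cells (adjusted p = 0.238) and 0.00 ± 0.067 in Th1 cells (adjusted p = 0.995), and Slc7a11 lay below the signal filter. Of 16 ferroptosis promoters 1 rose in each cell type, Cybb, the NADPH oxidase subunit gene, by 0.67 ± 0.080 and 0.87 ± 0.080 (list adjusted p = 0.609 and 0.603, fry 0.113 and 0.0461). Acsl4 had -0.26 ± 0.192 and 0.32 ± 0.192 and did not pass. Antioxidant defence genes rose in 4 of 23 in Tfh cells (adjusted p = 0.827, fry 0.0441), and rose in 1 and fell in 2 in Th1 cells (adjusted p = 0.586, fry 0.227), with the peroxiredoxin gene Prdx4 higher in both (0.47 and 0.33) and Gpx1 lower in Th1 cells (-0.19). The Tfh and Th1 lists in this paragraph had adjusted p of 0.636 to 0.941 with an estimated correlation.

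Mitochondrial dynamics and mitophagy genes rose in 1 of 18 in Tfh cells, the fusion gene Mfn2 (0.25), and 0 passed limma in Th1 cells with 3 at an unadjusted p under 0.05 (camera adjusted p = 0.707 and 0.459, fry 0.0645 and 0.171). Fatty acid oxidation genes rose in 2 of 17 in Tfh cells, and rose in 1 and fell in 1 in Th1 cells (adjusted p = 0.244 and 0.9, fry 0.0596 and 0.859), with Decr1 at 0.36 and 0.25. Of 18 genes of the integrated stress and unfolded protein response 2 rose in Tfh cells, Ddit3 (0.31) and Eif2ak3 (0.25), and 0 passed limma in Th1 cells with 3 at an unadjusted p under 0.05 (camera adjusted p = 0.535 and 0.129, fry 0.039 and 0.134). Of 44 ribosomal protein genes 2 rose in Tfh cells, Rps6 (0.46) and Rps4l (0.36), and 2 fell in Th1 cells, Rpl12 (-0.35) and Rps25 (-0.29), with adjusted p = 0.535 and 0.297 (fry 0.0676 and 0.0769). T cell identity genes rose in 2 of 13 in Tfh cells, Skap1 (0.24) and Cd2 (0.22), and 1 fell in Th1 cells, Lat (-0.30), with adjusted p = 0.601 and 0.189 (fry 0.538 and 0.171). Klf2, a factor of T cell recirculation, was lower in Tfh than in Th1 cells by -0.28 ± 0.071 in both genotypes. That Klf2 call ended with each array of the WT groups left out in WT cells (adjusted p of 0.0876 to 0.18), and in Rictor-null cells after quantile normalization (0.0692) or without Rictor-null Tfh replicate 1 (0.0926), Rictor-null Th1 replicate 1 (0.227), WT Tfh replicate 1 (0.0629) or WT Tfh replicate 2 (0.0628).

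Markers of other cell types gave these values between the genotypes. Averaged over both cell types, shorter sets of markers had a median of 0.083 for B cells (6 markers), -0.052 for myeloid cells (8) and -0.0445 for erythroid cells (2), of which 3, 5 and 1 lay below the signal filter. Of the genes in the lists, 1 of 12 CD8 T and NK cell markers, 3 of 12 regulatory T cell markers, 9 of 26 Tfh signature, 8 of 28 Th1 signature and 8 of 13 inhibitory receptor genes are also in another list. B cell and plasma cell markers rose in 2 of 8 in Tfh cells, Ighm (0.28) and Cd74 (0.23), and in Th1 cells Cd74 rose (0.41) while Cd22 (-0.57) and Ighm (-0.32) fell (adjusted p = 0.946 and 0.577, fry 0.416 and 0.493). Myeloid and dendritic cell markers rose in 2 of 13 in each, with Lgals3 at 0.74 and 0.94 (adjusted p = 0.946 and 0.9, fry 0.0308 and 0.0657). Erythroid and platelet markers rose in 1 of 6 in each, Car2 at 0.61 and 1.09, and fell in 1 in Tfh cells, Epor at -0.26 (adjusted p = 0.474 and 0.875, fry 0.738 and 0.0678). Th17 and Th2 markers rose in 1 and fell in 1 of 5 in Tfh cells, and rose in 3 and fell in 1 in Th1 cells, with Gata3 at 0.24 and 0.45 (adjusted p = 0.19 and 0.168, fry 0.0968 and 0.0122). For memory and quiescence, T cell identity, B cell and erythroid markers in Tfh cells, and for mTOR and AKT components, fatty acid oxidation, myeloid and erythroid markers in Th1 cells, the median of the list was negative and its mean positive.

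Of the sex-linked genes Xist was at signals of 5172 to 5748 on the 8 arrays on its brightest probe set. There it did not pass between genotypes (0.08 ± 0.054 in Tfh cells, 0.09 ± 0.054 in Th1 cells), while the interaction passed without probe sets that can cross-hybridise, as given above. Eif2s3y, Kdm5d and Uty lay below the signal filter.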
